A study of Marvinbryantia formatexigens DSM 14469 and Blautia hydrogenotrophica DSM 10507 and Bacteroides thetaiotaomicron VPI-5482 with 119 samples.

How the data were processed

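The series holds 119 RNA sequencing libraries of 3 gut bacteria and of Escherichia coli, in 65 groups of analysis. The bacteria are Bacteroides thetaiotaomicron, a polysaccharide-degrading gut symbiont, and the acetogens Marvinbryantia formatexigens and Blautia hydrogenotrophica, which make acetate from one-carbon compounds by the Wood-Ljungdahl pathway. There were 19 libraries of cecal contents or fecal pellets from C57Bl6 mice on a chow rich in polysaccharides, colonised with B. thetaiotaomicron alone or with 1 of the acetogens. The other 100 libraries came from cultures or from trials of RNA preparation. Per the labels' protocols, samples were frozen, treated with an RNA stabiliser, made into cDNA libraries with an Illumina genomic DNA kit and sequenced on a Genome Analyzer.

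Each library had 1 file of coding sequences. Per the file headers, the deposited values were hits per coding sequence, a fraction of reads and an average match score. The deposited hits were expected counts, since a read with tied hits was split between features, and 3.08% of them were not whole within a tolerance of 0.01. They were rounded to whole numbers before the tests, and their sums stayed within 1.5 of the coding reads stated per the file headers. The deposited fraction equals hits over coding reads and was used only to check the totals. The deposited score had a highest value of 32 or 36 by library and served only to look for sequencing batches. The closing lines also gave reads on rRNA, tRNA, intergenic sequence and adapter, per the file headers. The aligner and genome build are not given in the sources used here. Whether counting used strand is also not given, so reads of overlapping or antisense genes cannot be told apart. Genes with near-identical copies, such as transposases, share reads and are uncertain.

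Genes are named by the locus tags in the files. The files pair tags of B. thetaiotaomicron, M. formatexigens and E. coli with the first word of a product name, given here in quotation marks. For B. hydrogenotrophica all 3831 genes carry the word "hypothetical", so the files do not pair its tags with products and gene lists were not analysed here. Lists for the other organisms were chosen before the data were examined, as were the comparisons, tests and alternatives unless stated otherwise. The lists built on product names had to be applied to first words alone, a change made after the file format had been seen and before counts were compared. Those lists were ribosomal proteins, chaperones and heat shock, the Wood-Ljungdahl pathway, hydrogenases, Rnf and NADH-linked electron transport, glycolysis, the phosphotransferase system, sugar ABC transporters, glycoside hydrolases, amino acid biosynthesis, amino acid and peptide transport, sporulation, and transposases and phage. For B. thetaiotaomicron, capsular, starch, fructan, pectin and arabinogalactan, alpha-mannan and host glycan loci were ranges of locus tags. A list of ethanolamine and propanediol utilisation was added after the file format had been seen and before counts were compared. Lists of formate metabolism, amino acid catabolism, flagella and SusC and SusD homologues could not be drawn from first words and were not analysed here.

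Counts were compared within 8 families of libraries with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with a minimum count of 10, TMM factors scaled the libraries, and robust quasi-likelihood F tests gave p-values adjusted by the Benjamini-Hochberg method. A gene passed at an adjusted p under 0.05. Where no gene differs, a share of about 0.05 of the tested genes still reaches an unadjusted p under 0.05. Standard errors of log2 fold changes are the fold change divided by the root of its F statistic. Levels are CPM (counts per 1e+06) of coding reads of the organism, scaled by TMM. Gene lists with at least 5 tested members were compared with the other genes by limma 3.58.1 camera on voom values with a preset correlation of 0.01, and again with an estimated correlation. The limma test fry asked whether members moved on balance one way. Both were two-sided and adjusted over the lists of a comparison. Beside each list stands the number of members passing when adjusted over the list alone. Folds against a group without any read are lower bounds against a floor of 3 counts over the group. Where a group held 1 to 3 reads, the ratio of pooled reads is given with an exact 95% interval from the binomial distribution. Shares of reads carry exact Clopper-Pearson 95% intervals where 1 library is reported. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Shares in cecum and feces were compared with exact permutation tests in scipy 1.17.1 under Python 3.11, and plots were drawn with matplotlib 3.10.9.

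Groups followed the titles. B. hydrogenotrophica fructose 2 and phenylalanine 2 carry descriptions of pyruvate and isoleucine, and the N2/CO2 libraries 5 and 6 carry a description of M. formatexigens in formate medium, although their coding reads lay on B. hydrogenotrophica genes. Cecal library 11 with M. formatexigens and its repeat carry a description of B. hydrogenotrophica, although 137158 and 134663 of their coding reads lay on M. formatexigens genes and 0 on B. hydrogenotrophica genes. B. hydrogenotrophica pyruvate 1 was harvested at an A600 of 1.8, that of stationary cultures, and pyruvate 2 at 0.5. Genes were named by a rule. It took up to 10 genes each way with the largest fold change among those passing with a mean of at least 50 CPM and no overlap of replicate values, or up to 3 each way for single carbon sources and depletion. It also took up to 3 members of each list with the smallest p, and runs of at least 4 neighbouring tags that passed in one direction. Of these, the text names the ones with a product word or a clear place in a run. The labels do not say whether replicate cultures were grown independently or whether numbers shared between cecum and feces mark one mouse. Deviations from group means correlated at 0.031, 0.096, 0.074 and 0.168 over genes for the 4 shared mouse numbers. The highest values with another number of the same colonisation were -0.031, 0.066, -0.015 and -0.029. The shared number was the higher each time, which leans towards one mouse per number, but the values were low. The numbers were not taken as pairs, so some libraries counted as independent may come from one mouse. The p-values rest on the spread between libraries within groups, whatever its source, estimated jointly over the groups of a family. A group whose libraries disagree more than the others is therefore not judged by its own spread alone.

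Alternatives were DESeq2 1.42.0, relative log expression (RLE) factors, no filter on low counts, leaving out each library in turn, title numbers as a block, repeat cecal libraries added to their first library, only the groups compared, all depleted libraries of an acetogen in one fit, libraries with a conflicting carbon source or medium left out, and depletion fits with no covariate or with rRNA in the library size. After the data were seen, fits without the 2 shallowest sugar libraries, a fit of the 8 libraries of the block without the block, and the contrasts of feces and cecum within each acetogen were added. On simulated counts for the real libraries with known changes, edgeR recovered 40% of genes changed 4-fold for B. thetaiotaomicron with and without B. hydrogenotrophica in cecum, 10.8% for M. formatexigens in cecum against culture, 65.2% for B. hydrogenotrophica in cecum against culture, 84.5% for M. formatexigens on fructose, 90.8% for B. hydrogenotrophica on fructose, 95.9% for low formate, 22.7% for hydrogen and 32% for the custom depletion. The 3 repeat cecal libraries, 4 undepleted acetogen cultures, 14 single preparation libraries of B. thetaiotaomicron and 2 of E. coli stayed out of the comparisons.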

Results

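RNA of 3 gut bacteria was sequenced from mice and from cultures. Mice carried B. thetaiotaomicron alone (3 cecal and 2 fecal libraries), with B. hydrogenotrophica (3 and 3) or with M. formatexigens (2 and 3). M. formatexigens was grown on glucose and 15 other carbon sources, to stationary phase on glucose, and in minimal medium with 3 levels of formate, with 2 libraries in each group. B. hydrogenotrophica was grown on glucose (3 libraries), on 7 other carbon sources and to stationary phase (2 each), and on glucose under H2/CO2 (4), N2/CO2 (4) or N2 alone (5). B. thetaiotaomicron in rich TYG medium gave 8 libraries of an rRNA depletion trial. Reads on coding genes ranged from 126879 to 1868309 in mouse libraries and from 59745 to 1911403 in the 72 depleted acetogen cultures.

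Ribosomal RNA took 71.2% ± 13.9 (SD, n = 8, repeat libraries left out) of the reads on features in cecal libraries and 65.4% ± 12.5 (SD, n = 8) in feces. It took 29.5% ± 11.2 (SD, n = 72) in depleted acetogen cultures and 92.2% ± 1.30 (SD, n = 4) in undepleted ones. Acetogen genes were covered thinly in some libraries, with 16561 B. hydrogenotrophica reads in cecal library 7 and 36679 M. formatexigens reads in cecal library 13. The highest match score was 36 in the mouse libraries except fecal library 15 and 32 in cultures of the 3 bacteria. Whether the score marks a sequencing batch is not given. If it does, mouse and culture cannot be told apart from it for B. hydrogenotrophica and for M. formatexigens in cecum. In feces 1 of the 3 M. formatexigens libraries had the score of the cultures.

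The titles raise the question of how much of the community's transcript pool each acetogen held. M. formatexigens genes took 28.6% ± 0.367 (SD, n = 2) of coding reads in cecum and 43.0% ± 9.64 (SD, n = 3) in feces. B. hydrogenotrophica genes took 15.6% ± 6.68 (SD, n = 3) in cecum and 29.0% ± 10.7 (SD, n = 3) in feces. Neither difference passed a two-sided exact permutation test, with p = 0.2 for both acetogens, where the smallest possible p was 0.2 for M. formatexigens and 0.1 for B. hydrogenotrophica. As a share of all reads on features, with rRNA included, M. formatexigens took 3.91% in cecum and 12.5% in feces, and B. hydrogenotrophica 2.32% and 3.80%. These means were not tested, and single libraries overlapped. M. formatexigens had a lower share in fecal library 13 (146686 of 4023807 reads) than in cecal library 11 (137158 of 2202780). B. hydrogenotrophica had a lower share in fecal library 8 (58061 of 2936206) than in cecal library 9 (209175 of 4526538).

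**Figure D1:**
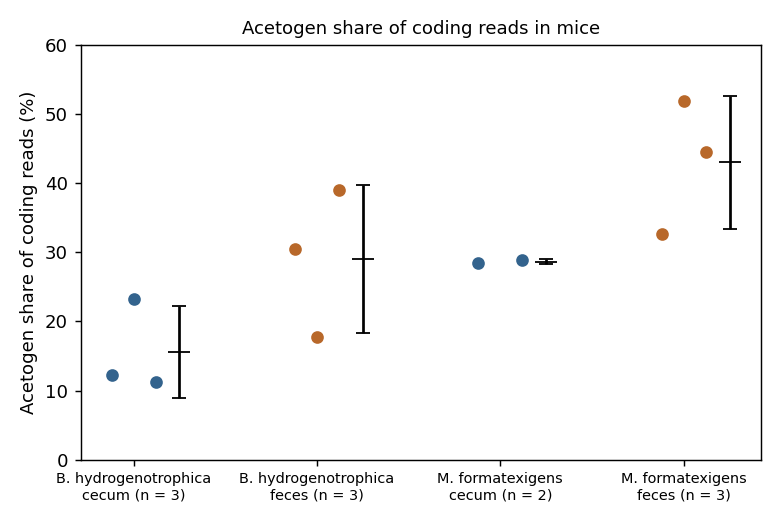
Each point is the share of coding reads on acetogen genes in 1 mouse library (percent, vertical axis), by acetogen and compartment, with bars for the mean and SD. M. formatexigens lay between 28.4% and 28.9% in cecum and between 32.7% and 51.8% in feces, and B. hydrogenotrophica between 11.2% and 23.2% in cecum and between 17.7% and 39.0% in feces.

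Whether an acetogen goes with a different B. thetaiotaomicron transcriptome was asked in 3302 genes of 16 libraries. With B. hydrogenotrophica in cecum, BT2807 ("hypothetical") fell by 4.97 ± 0.88 on the log2 scale and BT2809 ("putative") fell by 4.42 ± 0.771 (edgeR adjusted p = 0.0321 each, n = 3 and 3). These neighbours were the only genes to pass edgeR, and both calls ended without Bt cecum 1 or without any 1 of the libraries with B. hydrogenotrophica 7, 8 or 9. The counts without them were 0 (Bt 1), 0 (library 7), 0 (library 8) and 9 (library 9), and leaving out Bt cecum 2 or 3 gave 8 or 5. DESeq2 called 13 genes, and 105 reached an unadjusted p under 0.05 in edgeR. In feces 0 genes passed edgeR, with 120 at an unadjusted p under 0.05 and 7 by DESeq2. The test of a difference of this effect between compartments gave 0 genes by edgeR, 54 at an unadjusted p under 0.05 and 2 by DESeq2, and 2 by edgeR without Bt cecum 2. RLE factors moved the median of all genes in that test from 0.0505 to -0.0907. Without a member passing, camera placed the starch locus higher in cecum (adjusted p = 1.63e-05) and chaperones lower and host glycan loci higher in feces (adjusted p = 0.00745 each). With an estimated correlation these adjusted p-values were 0.625, 0.319 and 0.598.

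With M. formatexigens, a run of genes annotated "Fe3+", "putative" and "hypothetical", BT1952 to BT1957, fell in cecum by a median of 4.78 on the log2 scale, and BT1951 to BT1957 fell in feces by a median of 4.64. BT1952 lost its call in cecum without library 11 (adjusted p = 0.374). BT1957 fell by 5.03 ± 0.606 in cecum (adjusted p = 4.48e-05) and by 4.89 ± 0.514 in feces (adjusted p = 3.93e-06), and BT1956 fell by 4.63 ± 0.523 and 4.64 ± 0.452. A second run, BT3188 to BT3192, which holds a "TonB" gene, fell by medians of 2.93 and 2.82. The calls of its ends were lost in cecum without library 11 or Bt cecum 1 or 2, and in feces without Bt feces 4 or library 14 (adjusted p from 0.0692 to 0.864). The "transcriptional" gene BT2372 fell by 4.50 ± 0.731 and 5.05 ± 0.648. BT3440 rose by 3.06 ± 0.502 in cecum and by 2.97 ± 0.561 in feces, beside BT3439 (2.54 ± 0.58 and 3.33 ± 0.673). In edgeR 21 genes passed in cecum, 3 higher and 18 lower (n = 2 and 3), and 45 in feces, 10 higher and 35 lower (n = 3 and 2).

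In the capsular polysaccharide loci, which encode surface glycans, BT1654 ("polysialic") rose by 3.67 ± 0.776 and BT1651 ("pyrophosphorylase") by 3.50 ± 0.755 in feces with M. formatexigens, and 61 of the 63 tested members did not pass (13 passed adjusted over the list alone). The "xylanase" gene BT1008, for a plant cell wall glycan, fell in cecum and fell by 3.17 ± 0.562 in feces. The camera test placed transposases and phage lower (adjusted p = 0.000173 in cecum and 0.000392 in feces), with 0 members passing (7 and 0 adjusted over the list alone), and with an estimated correlation the adjusted p was 0.165 and 0.257. The fructan locus was placed lower in cecum, with a median of -2.64 (adjusted p = 0.0101, and 0.414 with an estimated correlation), and 1 member passed adjusted over the list alone. Ribosomal proteins were placed higher in feces (adjusted p = 0.000168, and 0.828 with an estimated correlation) with 0 of 52 members passing and 0 adjusted over the list alone. Without cecal library 11 the cecal count was 5, and BT2372, BT3439 and BT1008 no longer passed. BT3439 also missed in cecum without Bt cecum 2 or 3 (adjusted p = 0.123 and 0.223), and BT1008 without Bt cecum 1 or 2 or cecal library 13 (adjusted p = 0.0838, 0.0847 and 0.267). BT1957 and BT1956 passed with each library left out. Without Bt fecal libraries 1 or 4 or fecal library 14, 26, 18 and 22 genes passed in feces, and BT1654, BT1651 and BT3439 no longer passed without Bt feces 1 or 4, at adjusted p from 0.0811 to 0.299. BT3440 missed in feces without Bt feces 1 (adjusted p = 0.186) and BT1651 also without fecal library 14 (adjusted p = 0.141). DESeq2 called 65 and 83 genes, and RLE factors gave 27 in cecum with 33.3% of them higher, against 14.3% with TMM. The test of a difference between compartments gave 0 genes by edgeR, 61 at an unadjusted p under 0.05 and 0 by DESeq2. In that test camera called the ribosomal (adjusted p = 6.3e-07), pectin (0.000288), fructan (0.00357) and glycolysis (0.029) lists without a passing member, and with an estimated correlation their adjusted p was 0.433 or higher.

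Between feces and cecum, averaged over the 3 colonisations, 805 B. thetaiotaomicron genes differed, 417 higher and 388 lower in feces (n = 8 and 8, edgeR). The run BT2419 to BT2425, which holds a "two-component" gene and K+ uptake genes, rose by a median of 7.78 on the log2 scale. Its "potassium-transporting" gene BT2425 rose by 8.85 ± 0.791 (adjusted p = 5.11e-07) and "K+-transporting" BT2424 by 7.78 ± 0.861. The "lysine-sensitive" gene BT1901 rose by 8.52 ± 0.856 and "hypothetical" BT0779 by 6.35 ± 0.459, to 14890 CPM. The runs BT0711 to BT0720 ("F0F1", the ATP synthase) and BT4058 to BT4068 ("NADH") rose by medians of 2.16 and 2.92, and BT0539 to BT0555 ("glutamine", "ammonium", "asparagine", "glutamate") by a median of 2.04. BT0555 lost its call without Bt cecum 2, Bt feces 1 or 4, fecal library 8 or cecal library 11 (adjusted p from 0.0524 to 0.143), and BT4058 without cecal library 11 (adjusted p = 0.0674).

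By list, 5 of 7 chaperones rose in feces (6 adjusted over the list alone), among them BT1830 ("co-chaperonin", 1.99 ± 0.279) and BT1829 ("chaperonin", 1.85 ± 0.262), with camera adjusted p = 0.00043 and 0.0609 with an estimated correlation. In glycolysis 4 of 15 rose and 1 fell (6 over the list alone), led by BT2430 ("hexokinase", 2.98 ± 0.367), with camera adjusted p = 0.00187 and 0.117 with an estimated correlation. Of Rnf and NADH-linked genes, which pass electrons to the membrane, 9 of 21 rose and 2 fell (12 over the list alone), with camera adjusted p = 0.00501 and 0.288 with an estimated correlation. In amino acid biosynthesis 4 of 39 rose (4 over the list alone), among them BT1902 ("pyrroline-5-carboxylate", 5.79 ± 0.637), with camera adjusted p = 0.0328 and 0.388 with an estimated correlation. Ribosomal proteins rose in 2 of 52 (0 over the list alone), with camera adjusted p = 0.0428 and 0.677 with an estimated correlation. Transposases and phage rose in 5 and fell in 3 of 33 (8 over the list alone), capsular loci rose in 1 and fell in 4 of 63 (1 over the list alone), and 1 of 8 starch locus genes rose, BT3704 ("alpha-amylase", 1.96 ± 0.376, 1 over the list alone). None of these last lists passed camera, with adjusted p = 0.184, 0.181 and 0.239.

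In the alpha-mannan loci, for yeast cell wall glycans, 21 of 38 genes fell in feces and none rose (28 adjusted over the list alone), led by BT3787 (-5.02 ± 0.587), with camera adjusted p = 1.08e-09 and 0.00154 with an estimated correlation. In host glycan loci 20 of 37 fell and none rose (22 over the list alone), among them BT2821 (-2.66 ± 0.455) and BT4244 (-1.51 ± 0.282), with camera adjusted p = 9.66e-07 and 0.0609 with an estimated correlation. In the fructan locus 8 of 11 fell (9 over the list alone), with "fructokinase" BT1757 at -1.91 ± 0.382 and "glucose/galactose" BT1758 at -3.05 ± 0.715, camera adjusted p = 0.00208 and 0.183 with an estimated correlation. Of glycoside hydrolases 28 of 114 fell and 6 rose (36 over the list alone), with "pullulanase" BT4689 at 3.15 ± 0.317, camera adjusted p = 0.00054 and 0.117 with an estimated correlation. Pectin and arabinogalactan loci held both directions, 20 of 84 higher and 12 lower (34 over the list alone), with BT4671 at 2.38 ± 0.264 and "arabinogalactan" BT4668 at 2.19 ± 0.268, and camera adjusted p = 0.62. In the 8 libraries whose title numbers recur in both compartments, 418 genes passed in a fit chosen after seeing the data, with no term for colonisation.

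What M. formatexigens expresses in the gut was set against exponential glucose culture in 2690 genes. Some genes for sugar uptake and breakdown were among those higher in mice. The "alpha-glucosidase" gene BRYFOR08044 had 1528 reads in cecum and 6524 in feces against 1 read in glucose culture, ratios of 18700 (95% interval 3350 to 738000) and 22600 (4060 to 895000). The "arabinose-binding" gene BRYFOR05014 rose by 10.14 ± 0.958 in cecum and 11.91 ± 1.01 in feces, and "alpha-N-arabinofuranosidase" BRYFOR05011, which releases arabinose, by 7.45 ± 0.756 and 7.93 ± 0.751. The "ABC" gene BRYFOR09759, in a run with an "alpha-galactosidase" gene, rose by 11.05 ± 1.03 and 10.95 ± 1.02, and "beta-glucuronidase" BRYFOR09207 by 7.25 ± 0.698 in cecum. In edgeR 904 genes passed in cecum, 450 higher and 454 lower (n = 2 and 2), and 1069 in feces, 537 higher and 532 lower (n = 3 and 2).

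Folds of 94 passing genes in cecum and 48 in feces had a group without a read. Of 40 sugar ABC transporter genes, 20 rose and 4 fell in cecum and 22 rose and 4 fell in feces (27 and 27 adjusted over the list alone). Of 65 glycoside hydrolases, 23 rose and 3 fell in cecum and 22 rose and 4 fell in feces (27 and 26 over the list alone). A run of 22 genes, BRYFOR07160 to BRYFOR07181, rose by a median of 3.23 in cecum and 3.37 in feces, where BRYFOR07181 missed without glucose 2 (adjusted p = 0.0587). It holds genes for ethanolamine and propanediol utilisation, by which bacteria break down membrane lipid and fucose products in protein shells. Of that list 13 of 15 rose in cecum and 14 of 15 in feces (13 and 14 over the list alone), with "PduT" BRYFOR07164 at 3.42 ± 0.481 and 3.39 ± 0.461. Camera adjusted p-values in cecum and feces were 0.000114 and 0.000274 for transporters, 0.000145 and 0.00393 for hydrolases, and 2.34e-09 and 1.17e-07 for ethanolamine and propanediol. With an estimated correlation no list held in either compartment, and these adjusted p-values were 0.332 and 0.372, 0.323 and 0.372, and 0.23 and 0.291. The fry adjusted p-values were 0.0236 and 0.00954, 0.00491 and 0.00595, and 0.00491 and 0.00257.

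Against glucose culture, 47 of 63 M. formatexigens ribosomal protein genes fell in cecum and 47 in feces, and 1 and 3 rose (49 and 54 adjusted over the list alone), with BRYFOR07440 at -3.46 ± 0.526 and -3.23 ± 0.42 and list medians of -2.44 and -2.11. With members lacking reads in one group set to their bound, the cecal median was -2.38. The 2 cecal libraries lay apart, at -10.04 (library 11) and -59.65 (library 13) on a first component with 60% of the variance. The glucose libraries lay at 89.05 and 92.71 on it. Of 34 amino acid and peptide transport genes, 19 fell in cecum and 19 in feces (22 and 20 over the list alone), with "oligopeptide" BRYFOR08085 at -6.14 ± 0.602 in feces. Amino acid biosynthesis fell in 16 and rose in 4 of 48 genes in cecum, and fell in 18 and rose in 3 in feces (21 and 22 over the list alone). Camera adjusted p-values in cecum and feces were 1.91e-10 and 3.47e-10 for ribosomal proteins, 1.36e-05 and 1.62e-06 for peptide transport and 0.00869 and 0.0164 for amino acid biosynthesis. With an estimated correlation these adjusted p-values were 0.23 and 0.291, 0.23 and 0.291, and 0.332 and 0.372. For each of these lists the match score, which may mark a sequencing batch, also differed between mouse and culture, except that fecal library 15 shared the score of the cultures.

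Of 11 Wood-Ljungdahl genes 0 passed edgeR in cecum (0 adjusted over the list alone) and 3 rose in feces (3 over the list alone), the "CO" genes BRYFOR06358 (1.69 ± 0.53) and BRYFOR06357 (1.78 ± 0.589) and "formate--tetrahydrofolate" BRYFOR07447 (1.67 ± 0.571). In feces camera gave adjusted p = 0.00777 for that list, and 0.489 with an estimated correlation. With all depleted libraries of the organism in one fit, BRYFOR06358 (1.17, adjusted p = 0.0107) and BRYFOR07447 (0.95, adjusted p = 0.0153) also passed in cecum. Each of the 3 fecal calls ended without fecal library 14 or 15 or glucose library 1 or 2, at adjusted p from 0.0661 to 0.319. Of 7 Rnf and NADH-linked genes, a list drawn from first words, 1 fell in cecum and 3 in feces (1 and 3 over the list alone). Among them "NADH:ubiquinone" BRYFOR05342 was at -1.21 ± 0.421 in feces, a call lost with any 1 fecal or glucose library left out. Its cecal call was lost without cecal library 11 or glucose 2 (adjusted p = 0.215 and 0.157). Of 5 hydrogenases 1 rose in cecum, and 2 rose and 1 fell in feces (2 and 3 over the list alone), with "hydrogenase" genes BRYFOR06344 and BRYFOR06341 at 2.76 ± 0.505 and 2.94 ± 0.542 in feces. The cecal hydrogenase call, BRYFOR06341, was lost without cecal library 11 or either glucose library (adjusted p from 0.0956 to 0.24) and with all depleted libraries in one fit (0.0968). Chaperones rose in 1 of 10 in cecum and 8 of 10 in feces (1 and 8 over the list alone), with "heat" BRYFOR06690 at 3.53 ± 0.603 and 6.85 ± 0.673. Sporulation genes rose in 9 and fell in 4 of 24 in cecum, and rose in 11 and fell in 3 in feces (14 and 14 over the list alone), with "cotJB" BRYFOR08815 at 8.10 ± 0.875 and 6.97 ± 0.823. In glycolysis 4 of 16 rose and 4 fell in cecum, and 5 rose and 2 fell in feces (8 and 7 over the list alone). In the phosphotransferase system 1 and 2 of 6 rose (0 and 2 over the list alone), and among 24 transposases and phage genes 2 rose and 1 fell in cecum and 2 rose and 3 fell in feces (2 and 3 over the list alone). In cecum 492 genes passed without cecal library 11, and 502 or 453 without glucose library 1 or 2. In feces 556 or 472 passed without glucose library 1 or 2, and 1742 and 2121 passed in cecum and feces with all depleted libraries of the organism fitted at once.

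A direct contrast of feces with cecum within M. formatexigens, chosen after seeing the data, gave 8 genes by edgeR, all higher in feces (n = 3 and 2, adjusted p = 0.0298 each). They were K+ uptake genes, "K+-transporting" BRYFOR06152 (7.19 ± 1.14) and "potassium" BRYFOR06157 (4.51 ± 0.722), with "conserved" BRYFOR06158 (3.70 ± 0.639), and "dihydrodipicolinate" BRYFOR07333 (5.35 ± 0.787). The others were the stress proteins "heat" BRYFOR06690 (3.32 ± 0.571), "heat" BRYFOR09217 (3.22 ± 0.535) and "chaperone" BRYFOR07753 (2.90 ± 0.512), and "class" BRYFOR08067 (3.78 ± 0.658). Of 10 chaperones 3 rose (8 adjusted over the list alone), with camera adjusted p = 1.13e-09, 0.401 with an estimated correlation, and a fry adjusted p of 0.0389. No gene passed without cecal library 11 or without fecal library 14 or 15, 121 passed without cecal library 13, 22 without fecal library 13, and 38 by DESeq2. The same contrast in B. hydrogenotrophica gave 0 genes by edgeR (n = 3 and 3), 117 at an unadjusted p under 0.05 and 11 by DESeq2, and 8 without cecal library 9 or 18 without fecal library 10.

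**Figure D2:**
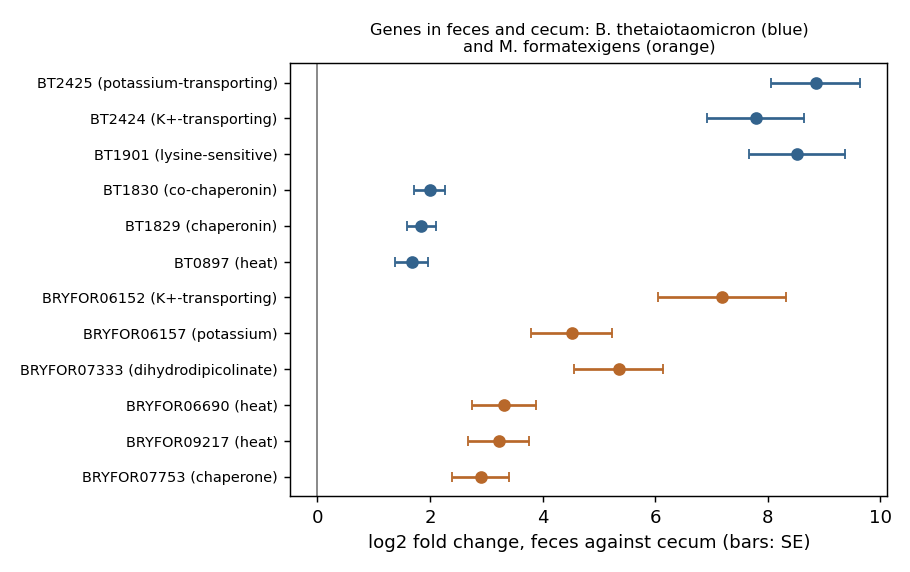
Points are log2 fold changes of feces against cecum with standard errors (horizontal axis) for genes of B. thetaiotaomicron (8 and 8 libraries) and M. formatexigens (3 and 2). They were picked by product words of K+ uptake, lysine synthesis and chaperones, and K+ uptake and lysine synthesis were not tested as sets. The genes were chosen among those that passed as higher in feces, and range from 1.67 for BT0897 to 8.85 for BT2425.

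Which M. formatexigens genes respond to the carbon source was asked in 3370 genes of 34 libraries, and 1838 differed among the 16 sources (edgeR F test). The comparisons below share the 2 glucose libraries. On fructose the run BRYFOR08171 to BRYFOR08176 rose by a median of 6.56, with its "sugar" gene BRYFOR08173 at 8.53 ± 0.602. On galactose BRYFOR05670 to BRYFOR05679 ("galactosidase", "cyclodextrin") rose by a median of 5.33, and on arabinose BRYFOR08158 to BRYFOR08166 ("ribulokinase", "L-ribulose-5-phosphate", "L-arabinose"), which hold enzymes of arabinose breakdown, rose by 2.40. The "ABC" gene BRYFOR08161 of that run rose by 7.57 ± 0.562 on arabinose and 7.43 ± 0.56 on galactose. On xylose BRYFOR07283 to BRYFOR07288 ("xylulokinase", the enzyme of D-xylulose) rose by 3.74 and BRYFOR05076 to BRYFOR05083 by 5.33. A "maltose-binding" gene, BRYFOR05140, fell by 3.92 ± 0.485 on fructose, by 6.55 ± 0.573 on galactose, by 7.32 ± 0.607 on arabinose and by 6.47 ± 0.56 on xylose. In edgeR 24 genes passed on fructose (13 higher), 238 on galactose (147 higher), 58 on arabinose (27 higher) and 59 on xylose (44 higher), n = 2 and 2 each. Without glucose 1 the counts on fructose, galactose and arabinose were 48, 53 and 105. Without fructose 1 there were 43, without galactose 1 or 2 there were 89 or 47, without arabinose 1 or 2 there were 35 or 24, and without glucose 2 there were 33 on arabinose. BRYFOR07288 lost its call on xylose without glucose 2 (adjusted p = 0.0692), and BRYFOR05670 on galactose without glucose 2 or either galactose library (adjusted p from 0.125 to 0.176).

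On N-acetylglucosamine 816 genes differed, 416 higher and 400 lower. BRYFOR05077 rose by 7.56 ± 0.832 and "sugar" BRYFOR05078 by 6.64 ± 0.868, 12 of 14 ethanolamine and propanediol genes rose (12 adjusted over the list alone), and 22 of 70 glycoside hydrolases rose and 3 fell (28 over the list alone). Camera gave adjusted p = 0.000135 for glycoside hydrolases and 0.0332 with an estimated correlation, and 2.55e-11 for ethanolamine and propanediol, 0.141 with an estimated correlation. Ribosomal proteins fell in 15 of 65 (15 over the list alone), with camera adjusted p = 4.22e-06 and 0.377 with an estimated correlation. Without N-acetylglucosamine 1 or glucose 2, 412 or 499 genes passed.

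On the glucose polymers a "glycogen" gene, BRYFOR06574, led. It rose by 5.45 ± 0.329 on maltose, 9.06 ± 0.377 on maltotriose, to 16470 CPM, and 6.53 ± 0.343 on maltodextrin. The "oligo-1,6-glucosidase" gene BRYFOR05103, which trims branched glucans, rose by 3.61 ± 0.424 on maltotriose. There BRYFOR05017 to BRYFOR05028 ("acyl", "malonyl", "3-oxoacyl-"), of fatty acid synthesis, fell by a median of 3.29. In edgeR 10 genes passed on maltose (4 higher), 143 on maltotriose (74 higher) and 14 on maltodextrin (12 higher). Without glucose 2 or maltose 1, 2 and 2 genes passed on maltose. Without glucose 1, maltotriose 1 or maltotriose 2, 20, 34 and 29 passed on maltotriose. On maltodextrin 27 or 2 passed without glucose 1 or 2, and 6 or 5 without maltodextrin 1 or 2. BRYFOR06574 passed in each of these fits, while on maltotriose BRYFOR05017 and BRYFOR05028 missed without glucose 1 or maltotriose 1, and BRYFOR05028 without maltotriose 2 (adjusted p from 0.0726 to 0.171).

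On trehalose, raffinose, sucrose and stachyose the run BRYFOR05654 to BRYFOR05659 ("alpha-galactosidase", "amylosucrase", "levanase"), of sucrose and galactoside breakdown, rose by medians of 6.02, 5.20, 5.04 and 7.36. Its "sugar" gene BRYFOR05657 rose by 7.67 ± 0.647 on trehalose, 6.94 ± 0.632 on raffinose and 6.85 ± 0.628 on sucrose. On melibiose and stachyose "sn-Glycerol-3-phosphate" BRYFOR09758, in the run with "alpha-galactosidase", rose by 10.84 ± 0.483 and 10.06 ± 0.478. On cellobiose "cellobiose-phosphorylase" run BRYFOR06861 to BRYFOR06874 rose by a median of 4.76 and "extracellular" BRYFOR05789 by 11.19 ± 1.69, and on lactose "beta-galactosidase" BRYFOR07218, which splits lactose, by 10.43 ± 0.624. The "D-xylose" gene BRYFOR07252 fell by 4.12 ± 0.728 on trehalose, by 3.57 ± 0.704 on cellobiose and by 4.64 ± 0.776 on stachyose. Ethanolamine and propanediol genes rose in 12 of 14 on cellobiose, 12 on melibiose and 13 on stachyose (12, 13 and 14 adjusted over the list alone), with camera adjusted p = 1.73e-14, 1.14e-17 and 2.61e-11, and 0.0686, 0.0695 and 0.146 with an estimated correlation. The 2 stachyose libraries lay apart, library 1 at 25.67 and library 2 at 77.67 on a first component with 19.9% of the variance, with 1042279 and 69835 coding reads. Glycoside hydrolases rose in 10, 12 and 16 of 70 on trehalose, cellobiose and stachyose and fell in 1, 1 and 5 (12, 17 and 28 over the list alone), and camera held with an estimated correlation at adjusted p = 0.0455, 0.00931 and 0.0065.

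In edgeR 148 genes passed on trehalose (75 higher), 238 on cellobiose (145 higher), 75 on lactose (38 higher), 110 on melibiose (70 higher), 52 on raffinose (20 higher), 634 on stachyose (317 higher) and 52 on sucrose (21 higher). Glucose 2 set several of these counts of carbohydrate response genes, with 45 on trehalose, 49 on cellobiose, 19 on lactose, 22 on melibiose and 20 on sucrose without it. Without glucose 1, 468 passed on cellobiose and 354 on stachyose. Without trehalose 2 there were 37, without lactose 1 or 2 there were 28 or 21, without melibiose 1 or 2 there were 44 or 48, without raffinose 1 or 2 there were 19 or 28, and without sucrose 1 or 2 there were 30 or 16. BRYFOR07252 lost its call on trehalose without trehalose 2 (adjusted p = 0.0512) and on cellobiose without glucose 2 (adjusted p = 0.0686), while BRYFOR05657, BRYFOR09758, BRYFOR05789 and BRYFOR07218 passed in each of these fits.

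**Figure D3:**
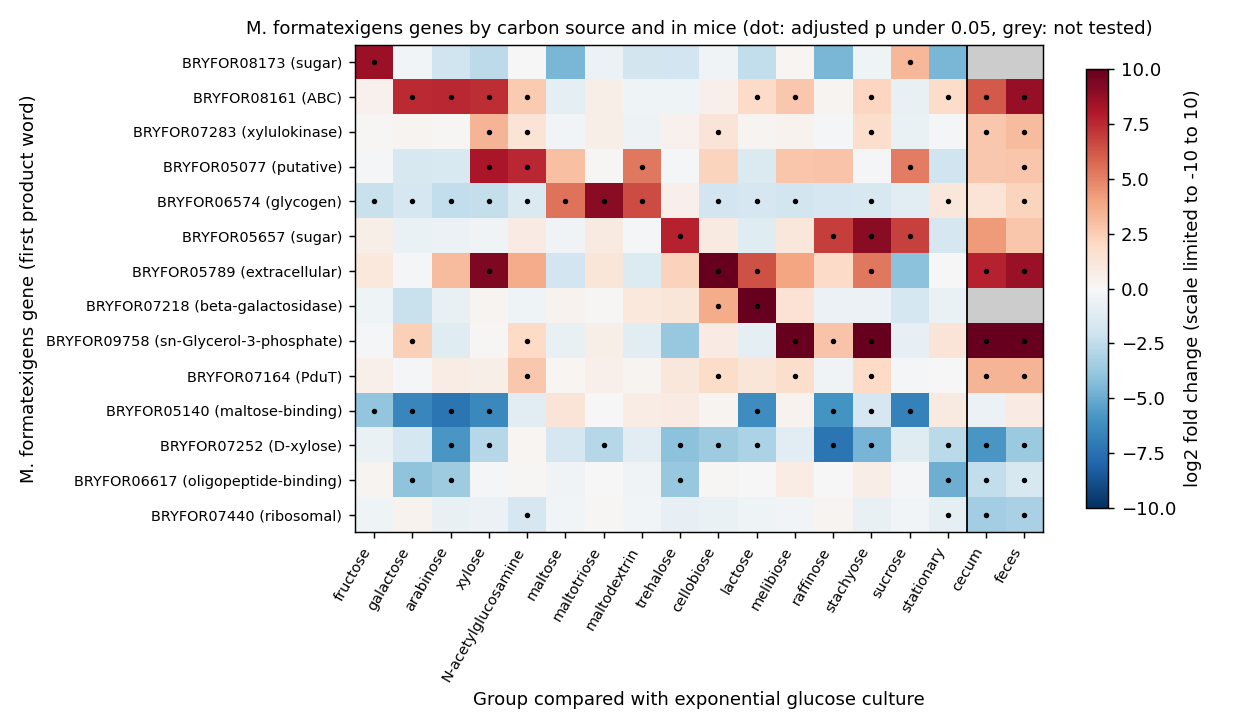
Colours are fitted log2 fold changes of 14 M. formatexigens genes (vertical axis) against exponential glucose culture for 15 carbon sources, stationary phase and mice (horizontal axis), dots mark an adjusted p under 0.05 in edgeR, and grey marks genes not tested in mice. BRYFOR06574 was highest on maltotriose (9.06), BRYFOR07218 on lactose (10.43) and BRYFOR07164 in mice (3.42 in cecum and 3.39 in feces).

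Growth phase was asked on glucose, where stationary culture at an A600 of 1.8 differed from exponential culture in 1493 genes, 723 higher and 770 lower (edgeR, n = 2 and 2). Of 65 ribosomal protein genes 50 fell and 4 rose (55 adjusted over the list alone), with a median of -2.07, camera adjusted p = 1.8e-13, and 0.52 with an estimated correlation. The neighbouring "ABC" and "sugar" genes BRYFOR06625 and BRYFOR06626 fell by 5.43 ± 0.319 and 5.86 ± 0.385, and "oligopeptide-binding" BRYFOR06617 by 4.87 ± 0.398. Of 7 Rnf and NADH-linked genes 5 fell (5 over the list alone), and in glycolysis 7 of 16 rose and 4 fell (12 over the list alone). The "conserved" genes BRYFOR07867 and BRYFOR08415 rose by 7.43 ± 0.668 and 6.79 ± 0.348, to 17430 and 17620 CPM. Ethanolamine and propanediol genes rose in 2 of 14 (1 over the list alone), with a median of 0.27.

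Formate, a substrate of the methyl branch of the Wood-Ljungdahl pathway, was added to glucose minimal medium at 4.5 mM or 45 mM. The "O-acetylhomoserine" gene BRYFOR08127, of methionine synthesis, fell by 4.70 ± 0.357 at 4.5 mM and by 4.72 ± 0.421 at 45 mM, and "carbon" BRYFOR08069 at both doses (by 2.87 ± 0.538 at 45 mM). At 4.5 mM "sugar-binding" BRYFOR08835 rose by 5.59 ± 0.677 and "glycogen" BRYFOR06574 from 85.07 to 683.7 CPM. At 45 mM "phage" BRYFOR07604 and BRYFOR07624 rose by 2.71 ± 0.303 and 2.14 ± 0.268, and "sensor" BRYFOR05830 by 2.42 ± 0.272. From 4.5 mM to 45 mM BRYFOR06574 fell by 2.04 ± 0.259 and BRYFOR07604 rose by 1.92 ± 0.283. Of 12 Wood-Ljungdahl genes 0 passed edgeR at either dose (5 at 4.5 mM and 0 at 45 mM adjusted over the list alone), while camera placed the list higher (adjusted p = 0.000169 and 0.000237, and 0.785 and 0.567 with an estimated correlation). The 45 mM libraries lay apart, at 27.25 (library 5) and 4.68 (library 6) on a first component with 36.5% of the variance. The 4.5 mM libraries lay at 4.28 and 1.58.

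Among 2953 genes tested, 107 passed at 4.5 mM (68 higher), 62 at 45 mM (39 higher) and 14 between the doses (4 higher), in edgeR with n = 2 in each group, and with no filter on low counts the numbers were 211, 158 and 37. Without no-formate library 1 or 2 the first count was 48 or 31 and the second 27 or 25, and without libraries 3 or 4 at 4.5 mM the first was 62 or 48. Between the doses 7, 5, 8 and 4 genes passed without libraries 3, 4, 5 and 6. BRYFOR08069 lost its call at 4.5 mM without no-formate library 1 or 2 (adjusted p = 0.058 and 0.0778), and at 45 mM also without library 5 or 6 (adjusted p from 0.103 to 0.256). BRYFOR07604 passed at 45 mM against no formate with each library left out, and lost its call between the doses without library 3, 4 or 6 (adjusted p = 0.0581, 0.0676 and 0.117). BRYFOR08127 and BRYFOR06574 passed in each fit.

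What B. hydrogenotrophica expresses in the gut was set against exponential glucose culture in 1687 genes, and the files do not pair its tags with products. The 13 passing genes of the run RUMHYD03366 to RUMHYD03379 rose in cecum by a median of 5.37, and 12 genes within it rose in feces by a median of 6.09. The run RUMHYD00276 to RUMHYD00285 fell by medians of 3.08 in cecum and 3.13 in feces. In edgeR 283 genes passed in cecum, 179 higher and 104 lower, and 249 in feces, 143 higher and 106 lower (n = 3 and 3). RUMHYD03366 lost its call in cecum without cecal library 8 or any glucose library (adjusted p from 0.0546 to 0.153). Without cecal library 9 the cecal count was 470, and without glucose 2 or 3 it was 164 or 187.

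Carbon source was asked of B. hydrogenotrophica in 2706 genes of 19 libraries, and 1477 differed among the 8 sources (edgeR F test). One run of 10 neighbouring genes, RUMHYD00546 to RUMHYD00555, moved in both directions. Its median was -3.45 on fructose, -5.92 on pyruvate and -6.14 on phenylalanine, and within runs of 11 genes it rose by 3.98 on isoleucine and 4.54 on valine. RUMHYD00546 fell by 5.88 ± 1.08 on pyruvate (adjusted p = 0.00173) and also passed without pyruvate 1, which was harvested at an A600 of 1.8 like the stationary cultures against 0.5 for pyruvate 2 and glucose. It rose by 4.33 ± 0.756 on isoleucine and 5.35 ± 0.787 on valine. On ribose it did not pass (-1.34 ± 0.753, adjusted p = 0.227), but passed without ribose 1 (-5.03 ± 0.678). The calls of the run's ends on fructose were lost without glucose 2 or 3 or fructose 1 or 2 (adjusted p from 0.051 to 0.224), and on phenylalanine without either of its libraries (0.0642 to 0.129). RUMHYD00555 missed on pyruvate without pyruvate 2 (adjusted p = 0.0646).

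On ribose a run of 14 genes, RUMHYD02243 to RUMHYD02257, rose by a median of 5.14. The calls of its ends were lost without glucose 2 or 3 or ribose 1 (adjusted p from 0.0709 to 0.73), and without ribose 1 RUMHYD02257 was at -0.44. The 2 ribose libraries differed widely within the run, where a gene was at 6313 ± 7290 CPM (SD, n = 2) on ribose. On tryptone the neighbours RUMHYD02980 and RUMHYD02981 rose by 5.58 ± 0.625 and 5.68 ± 0.651, and RUMHYD00276 to RUMHYD00285 fell by a median of 3.24. Its median was -3.51 on phenylalanine and -4.61 on isoleucine. In stationary culture 1276 genes differed from exponential glucose culture, 652 higher and 624 lower (n = 2 and 3), and the run from RUMHYD00546 to RUMHYD00555 fell within a longer run with a median of -4.36.

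The counts of B. hydrogenotrophica genes passing edgeR (n = 2 and 3) were 432 on fructose (260 higher), 474 on ribose (217 higher), 520 on pyruvate (274 higher), 235 on tryptone (105 higher), 541 on isoleucine (267 higher), 291 on phenylalanine (157 higher) and 351 on valine (174 higher). Leaving out 1 library moved several of these gene counts. Without glucose 1, 2 or 3 the count was 806, 134 and 164 on fructose and 902, 159 and 238 on ribose. Without library 1 or 2 of the source it was 42 and 104 on fructose, 302 and 262 on pyruvate (302 without the library of higher A600), 95 and 91 on tryptone, 284 and 266 on isoleucine, 72 and 149 on phenylalanine, and 148 and 100 on valine, and without ribose 2 it was 151. With fructose 2 and phenylalanine 2 left out for their conflicting descriptions, 45 passed on fructose, 271 on ribose, 236 on pyruvate, 156 on tryptone and 91 on phenylalanine.

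H2 is an electron donor for acetate formation from CO2, and its effect was asked in 2215 genes of cultures on glucose. Under H2/CO2 against N2/CO2, 0 genes passed edgeR (n = 4 and 4), with 117 at an unadjusted p under 0.05 and 6 by DESeq2. Under N2 alone against N2/CO2, 175 genes passed, 73 higher and 102 lower (n = 5 and 4). The run RUMHYD00546 to RUMHYD00555 fell by a median of 7.71 there, with RUMHYD00555 at -8.07 ± 1.78 (adjusted p = 0.0155). The neighbours RUMHYD01239 and RUMHYD01240 rose by 5.10 ± 1.21 and 4.76 ± 0.952. The N2 cultures were grown in another medium, so gas and medium cannot be told apart. Without N2/CO2 libraries 1, 3, 5 or 6 the count was 265, 103, 68 and 74, and without N2 libraries 1, 2 or MA3_1 it was 71, 92 and 70. RUMHYD00555 missed without MA3_1 (adjusted p = 0.0507), and RUMHYD00546 missed without any 1 library of either gas except N2/CO2 1 (adjusted p from 0.0558 to 0.0759). RUMHYD01239 missed without N2/CO2 3, 5 or 6 or N2 library 2 (adjusted p from 0.0511 to 0.0627). DESeq2 called 304 genes, and without N2/CO2 5 and 6, which carry a conflicting description, 18 passed. In that fit all 4 genes named here lost their calls.

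**Figure D4:**
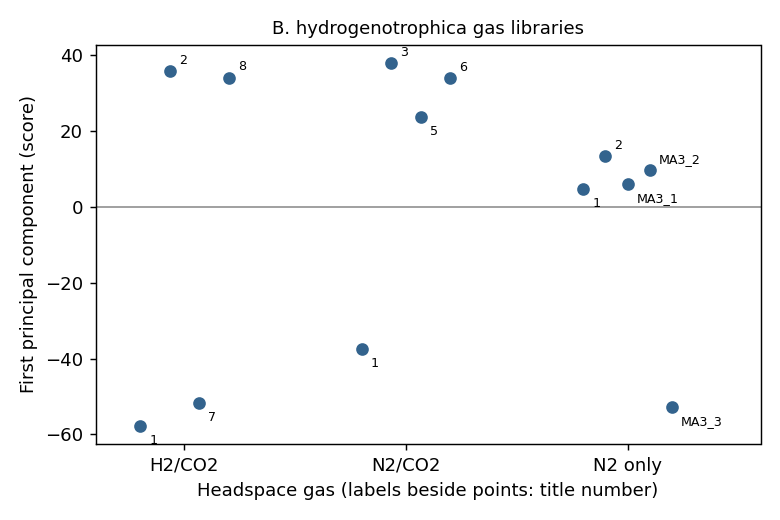
Points are scores of the B. hydrogenotrophica gas libraries on their first principal component (vertical axis, 45.2% of the variance) by headspace gas, with title numbers. Libraries of both CO2 gases lie at both ends, with H2/CO2 1 at -57.8 and N2/CO2 1 at -37.5 against H2/CO2 2 at 35.9 and N2/CO2 3 at 38.0.

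Whether rRNA depletion changes measured B. thetaiotaomicron transcripts was asked in 2010 genes in TYG medium, with the amount of input RNA in the fit. With the ME2x treatment ribosomal protein genes were lower, 14 of 52 passing lower and 1 higher (29 adjusted over the list alone), with a median of -1.77, camera adjusted p = 4.96e-10 and 0.563 with an estimated correlation. The 2 ME2x libraries lay apart, at 68.06 (library 3) and 5.87 (library 7) on a first component with 58.6% of the variance, where the other 6 lay between -24.9 and 15.7. The "30S" and "50S" run BT2713 to BT2719 fell by a median of 4.06. In capsular loci 8 of 55 genes fell and 1 rose (19 over the list alone), with camera adjusted p = 0.00147 and 0.595 with an estimated correlation. The "hypothetical" gene BT1357 rose by 4.39 ± 0.933, a call lost without undepleted library 1 (adjusted p = 0.211). With ME2x and custom2x together BT1958 rose by 5.66 ± 0.978 and BT2845 fell by 3.43 ± 0.59. In edgeR (n = 2 and 2) 138 genes passed for ME2x, 56 higher and 82 lower, and 2 for both treatments together. For custom2x 0 passed, with 35 at an unadjusted p under 0.05 and 1 by DESeq2.

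The ME2x gene count was 0 without the input amount in the fit, and 8, 213, 58 and 495 without undepleted library 1, undepleted library 5, ME2x library 3 and ME2x library 7. BT2713 and BT2719 missed without undepleted library 1 (adjusted p = 0.0966 and 0.077) and without the input amount (0.131 and 0.132). Both BT1958 and BT2845 missed without the input amount (adjusted p = 0.221 each) and without undepleted library 1 or library 4 or 8 of the joint treatment (adjusted p from 0.189 to 0.559), where the count was 0, and it was 9 without undepleted library 5. For custom2x, 2 and 1 genes passed without undepleted library 5 and custom2x library 6. The rRNA share was 82.0% ± 7.53 without depletion, 72.9% ± 0.978 with custom2x, 76.7% ± 4.10 with ME2x and 49.2% ± 7.23 with both (SD, n = 2 each, no test made). These means pool 2 amounts of input RNA. At 2.5 ug the share was 87.3% without depletion, 73.5% with custom2x, 79.6% with ME2x and 54.3% with both. At 10 ug it was 76.7%, 72.2%, 73.8% and 44.1%.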

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

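In this part, the tests of sequencing depth and of gas phase on the gas libraries, the test of growth phase on ethanolamine and propanediol genes, and the contrasts of feces with cecum within each acetogen were chosen only after the result was seen.

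The difference of M. formatexigens from glucose culture was not the same in feces and cecum for 8 genes by edgeR, all higher in feces (n = 3 and 2). This difference between the groups was tested directly. Among them are the genes named in the report with product words of K+ uptake, "dihydrodipicolinate" and heat or chaperone proteins. K+ uptake and lysine synthesis had no gene list and were not tested as sets. The count was 0 without cecal library 11 or without fecal library 14 or 15, 121 without cecal library 13 and 22 without fecal library 13.

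Libraries outside every comparison held signal on coding genes. The E. coli libraries had 28394 coding reads with exonuclease and custom2x treatment and 15682 without depletion. The B. thetaiotaomicron libraries of single preparations had 556 to 95848. Undepleted cultures had 31889 (B. hydrogenotrophica fructose 2), 264630 (B. hydrogenotrophica pyruvate 1), 298198 (M. formatexigens glucose 1) and 356474 (M. formatexigens xylose 2). Repeat cecal libraries had 460683 (library 11, with M. formatexigens), 172608 (library 7, with B. hydrogenotrophica) and 191365 (B. thetaiotaomicron alone, library 2). Within the 3 gas groups, the only groups of 4 to 10 libraries tested for a library far from the others, no library passed the critical value of its group on coding reads or rRNA share.

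The B. hydrogenotrophica gas libraries parted on a first principal component with 45.2% of the variance, along which H2/CO2 1 and 7, N2/CO2 1 and N2 MA3_3 lay between -57.8 and -37.5. Its highest loading was that of RUMHYD00546 (0.0897), in the run that carbon sources moved. Against sequencing depth as the cause stood a Spearman rho of -0.104 between component and coding reads over the 13 libraries (permutation p = 0.738). Against H2 as the cause stood the share of the component's sum of squares that lay between H2/CO2 and N2/CO2, 9.21% (exact permutation p = 0.343). Growth phase at harvest cannot be told apart from other causes, since rho between gene loadings and the stationary against exponential change was -0.238, although the labels give an A600 of 0.25 for each of these cultures but N2/CO2 5 and 6.

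The counts of genes by gas were set against other splits of the same libraries. For H2/CO2 against N2/CO2, where 0 genes passed edgeR (117 at an unadjusted p under 0.05 and 6 by DESeq2), the share of splits decides nothing, since a real count of 0 makes all 35 of 35 splits at least as large. The highest other count was 526, with H2/CO2 1 and 7 and N2/CO2 1 and 3 on one side, which points to a structure of the libraries other than gas. For N2 alone against N2/CO2, 1 of 100 splits, the real one, gave as many genes (175, the highest other 3). That is the smallest share 100 splits allow, so a chance split is unlikely but not excluded. The medium differed with the gas.

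B. hydrogenotrophica glucose library 1 stood apart from glucose 2 and 3, and without it the counts of genes on fructose and ribose were 806 and 902. Against a batch of libraries numbered 1 stood the correlation over genes of their deviations with that of glucose 1, a median of 0.018 over 8 groups. Growth phase stays open. Glucose 1 minus glucose 2 followed stationary minus glucose 3 at a rho of 0.472 (0.434 with glucose 2 and 3 exchanged, and -0.046 for glucose 2 minus glucose 3), so glucose 1 may have been further on in growth, although the labels give an A600 of 0.5 for all 3. A library of another carbon source also stays open, since glucose 1 correlated more with fructose 2 (0.942, described as pyruvate), fructose 1 (0.936) and ribose 1 (0.931) than with its nearest glucose library (0.927), a difference of -0.0148 for the first, and no test here set these explanations against each other.

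In mice M. formatexigens ribosomal protein genes were lower and ethanolamine and propanediol genes higher than in glucose culture. With an estimated correlation camera called neither list in either compartment. Against a few abundant genes as the cause of the ribosomal change, its median stayed at -2.12 in feces and -2.46 in cecum with 38 abundant genes left out. Against growth phase as the cause of the ethanolamine change, its rise in stationary against glucose culture was 11.7% of its rise in mice against the sugars other than glucose, some of which raise this list themselves (medians of 0.31 and 2.65 of differences in mean log2 level, which are not the fitted folds of the report). For ribosomal genes growth phase stays open, since mice minus the sugars other than glucose followed stationary minus glucose at a rho of 0.307 (0.346 in feces, 0.237 in cecum, and 0.287 without ribosomal genes), with list medians of -2.29 and -2.05. Slower growth in the gut may thus underlie the ribosomal change. A sequencing batch, if the match score marks one, cannot be told apart from mouse against culture in cecum for either list. Fecal library 15, with the match score of the cultures, lay at -32.12 on the first principal component, between the other mouse libraries (-59.65 to -10.04) and apart from glucose libraries (89.05 and 92.71), but 1 library does not exclude the batch in feces.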

How the results depend on the processing

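In this part, the tests without the 2 shallowest sugar libraries, the fit of the 8 numbered libraries with no block, and the contrasts of feces with cecum within each acetogen were chosen only after the result was seen. Of 550 counts and shares under other settings, 389 stayed within 1.5 times the reported count or 1 SD of the reported share and 161 moved beyond it. Some count moved in 40 of 47 gene comparisons. For 259 pairs of a gene and a comparison, which cover the genes named in the text and some others, 2663 of 2935 values under other settings kept direction and side of the threshold, 265 lost their call, 5 gained it and 2 reversed. Where no reason is given, the cause was not tested. Each alternative listed in the methods was run.

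Both reversals came from leaving out 1 ribose library. RUMHYD02257 rose by 2.24 on ribose and ranged from -0.44 without ribose 1 to 2.97 without ribose 2. RUMHYD00555, which did not pass, was at -0.48 and ranged from -5.94 without ribose 1 to 0.49 without ribose 2. Summed over all settings, genes passing in the reported fits took the opposite sign 77 times, whether or not they passed under the other setting.

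With DESeq2, 33 of 47 counts stayed and 14 moved. Its counts in mice were 65 in cecum and 83 in feces for B. thetaiotaomicron with M. formatexigens, 13 in cecum, 7 in feces and 2 between compartments with B. hydrogenotrophica, and for feces against cecum 38 in M. formatexigens and 11 in B. hydrogenotrophica. In cultures DESeq2 gave 93 on arabinose, 20 on maltose, 6 for H2, 304 for N2 alone, 212 for ME2x, 1 for custom2x and 13 for both treatments. RLE factors left 47 of 48 values and moved the count of B. thetaiotaomicron genes with and without B. hydrogenotrophica in cecum from 2 to 1. With no filter on low counts 36 of 47 stayed. The others were 33 and 1 in B. thetaiotaomicron cecum with M. formatexigens and with B. hydrogenotrophica, 66 and 16 in feces against cecum within M. formatexigens and B. hydrogenotrophica, 49 on lactose, 211 and 158 at 4.5 mM and 45 mM formate, 37 between the doses, 226 for ME2x, 4 for custom2x and 13 for both treatments.

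Fitting only the groups compared gave 63 genes in B. thetaiotaomicron cecum with M. formatexigens and 0 with B. hydrogenotrophica by edgeR. With all depleted libraries of an acetogen in one fit, M. formatexigens counts were 1742 in cecum, 2121 in feces and 369 between them, and B. hydrogenotrophica gave 9 between them. With repeat libraries added, 13 of 15 values stayed, B. thetaiotaomicron cecum with B. hydrogenotrophica gave 0 by edgeR (109 at an unadjusted p under 0.05) and M. formatexigens feces against cecum gave 3. As a share of all reads on features, whose total also holds rRNA, the B. hydrogenotrophica difference was 1.47 percentage points (3.80% in feces and 2.32% in cecum), with overlap of single libraries. With an estimated correlation camera called 5 lists in place of 91 of 438. These were alpha-mannan loci in B. thetaiotaomicron feces against cecum and glycoside hydrolases on N-acetylglucosamine, trehalose, cellobiose and stachyose.

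Without the conflicting libraries fructose 2 and phenylalanine 2, B. hydrogenotrophica counts were 45 on fructose, 271 on ribose, 236 on pyruvate, 156 on tryptone and 91 on phenylalanine, and without the pyruvate library of higher A600 there were 302. For N2 alone there were 18 genes without N2/CO2 5 and 6, 47 with the MA3 titles and 40 with the other titles, where fewer libraries were compared. Without raffinose 2 and stachyose 2, 16 passed on maltose and 33 on raffinose. With no input amount in the fit, ME2x and both treatments gave 0 by edgeR.

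Title numbers were not taken as pairs, since the labels do not say what they mark. As a replicate block they gave 144 genes on fructose and 185 on ribose for B. hydrogenotrophica, and 24 of 26 counts stayed. For B. thetaiotaomicron feces against cecum the block by title number gave 525 genes in 8 libraries, and the same 8 libraries with no block gave 418 against 805 in all 16. The fit with no block also left out colonisation, which the block and the fit of all 16 took in. The effects of set size, block and colonisation on the count were thus not separated.

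Leaving out 1 library in turn moved 108 of 307 counts and shares, and 211 of 1639 gene values lost their call. An arm left with 1 library was assumed to vary like the other groups. B. thetaiotaomicron counts ranged over 0 to 9 with B. hydrogenotrophica in cecum and 0 to 2 between compartments, 5 to 23 in cecum and 18 to 42 in feces with M. formatexigens, and 604 to 901 in feces against cecum. M. formatexigens counts in mice ranged over 453 to 828 in cecum, 472 to 1008 in feces and 0 to 121 between them. On its carbon sources they were 17 to 48 (fructose), 47 to 240 (galactose), 24 to 105 (arabinose), 41 to 71 (xylose), 412 to 705 (N-acetylglucosamine), 2 to 13 (maltose), 20 to 195 (maltotriose), 2 to 27 (maltodextrin), 37 to 195 (trehalose), 49 to 468 (cellobiose), 19 to 85 (lactose), 22 to 164 (melibiose), 19 to 49 (raffinose), 354 to 793 (stachyose) and 16 to 52 (sucrose). In stationary phase the range was 998 to 1260, among sources 1602 to 2208, and with formate 31 to 62 at 4.5 mM, 25 to 56 at 45 mM and 4 to 8 between the doses.

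For B. hydrogenotrophica the ranges without 1 library were 164 to 470 in cecum, 178 to 243 in feces, 0 to 18 between them, 68 to 265 for N2 alone, 42 to 806 (fructose), 151 to 902 (ribose), 262 to 648 (pyruvate), 91 to 230 (tryptone), 266 to 596 (isoleucine), 72 to 357 (phenylalanine), 100 to 365 (valine), 909 to 1427 in stationary phase and 1324 to 1668 among sources. For depletion they were 0 to 2 (custom2x), 8 to 495 (ME2x) and 0 to 9 (both). The feces minus cecum share ranged from 8.52 to 19.2 points for B. hydrogenotrophica and from 9.94 to 19.5 for M. formatexigens. The rRNA share against no depletion ranged from -14.5 to -3.83 points with custom2x, -10.7 to -0.033 with ME2x and -38.2 to -27.5 with both. Each of these differences compares unlike amounts of input RNA, so the ranges hold the effect of input as well. At matched input the share was lower with each treatment.

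Counts that stayed at 0 by edgeR without each library were those of B. thetaiotaomicron in feces with B. hydrogenotrophica (120 at an unadjusted p under 0.05, 7 by DESeq2), of the difference between compartments with M. formatexigens (61 and 0), and of H2 (117 and 6). What depth alone limits was not tested, since no setting varied it. In the mouse fits 2690 M. formatexigens and 1687 B. hydrogenotrophica genes had reads enough to be tested, against 3370 and 2706 in the fits of carbon sources. On simulated counts for the real libraries, in which group size and the spread between libraries differ as well as depth, edgeR recovered 10.8% of genes changed 4-fold in M. formatexigens cecum against culture, 22.7% for hydrogen and 40% for B. thetaiotaomicron with B. hydrogenotrophica in cecum, against 95.9% for low formate.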

Other observations

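In this part, the contrast of feces with cecum within B. hydrogenotrophica was, among the tests, chosen only after the result was seen. Further loci of B. thetaiotaomicron differed between feces and cecum as runs of neighbouring genes (n = 8 and 8, edgeR). The run BT0347 to BT0356 ("alpha-L-arabinofuranosidase", "L-arabinose", "L-ribulose-5-phosphate") rose in feces, with 9 passing at a median of 1.18 on the log2 scale. The run BT4665 to BT4672 ("arabinogalactan", "beta-galactosidase") rose with 8 passing at a median of 2.18. Runs that fell in feces were BT1036 to BT1050 (13 passing, median -1.77), BT2620 to BT2629 ("alpha-glucuronidase", 9 passing, median -1.71) and BT3983 to BT3994 ("endo-beta-N-acetylglucosaminidase", 10 passing, median -1.49). Some ends lost their calls with 1 library left out, BT0347 without Bt feces 1 or cecal library 13 (adjusted p = 0.0674 and 0.0728), BT3994 without these or Bt feces 4 (0.0552 to 0.0875), and BT2620 without Bt cecum 1 or 3, Bt feces 4, cecal library 9, 11 or 13 or fecal library 13 (0.0525 to 0.127).

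The M. formatexigens run BRYFOR05189 to BRYFOR05199, which holds "N-acetylneuraminate" and "N-acetylmannosamine-6-P" genes (N-acetylneuraminate is a sialic acid of host mucus and milk), rose in cecum against glucose culture with 10 passing at a median of 4.63, and to BRYFOR05198 in feces with 9 passing at 3.06. On lactose BRYFOR05193 to BRYFOR05199 rose with 7 passing at 2.87. Of these ends BRYFOR05199 missed in cecum without cecal library 11 or either glucose library (adjusted p from 0.0592 to 0.481), and BRYFOR05198 in feces without fecal library 14 or 15 or either glucose library (0.0521 to 0.224). On lactose BRYFOR05199 missed without glucose 1 and BRYFOR05193 without glucose 2 or lactose 2 (0.0627 to 0.126). The "conserved" gene BRYFOR07867, which rose in stationary culture, took 7.45% of M. formatexigens coding reads in cecal library 11 and 4.30% in fecal library 13. In cecal library 11 the 10 most abundant genes took 25.3% of M. formatexigens coding reads, against 20.3% in cecal library 13 and 13.2% to 20.4% in feces.

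The M. formatexigens culture most correlated with the cecal mean over 3710 genes was N-acetylglucosamine (Spearman 0.588), before stachyose (0.561), with galactose last (0.471). In feces it was N-acetylglucosamine again (0.604), before cellobiose (0.592), with galactose last (0.507). For B. hydrogenotrophica over 2996 genes isoleucine (0.755), tryptone (0.753) and valine (0.752) were nearest in cecum, and tryptone (0.795) and glucose (0.791) in feces, with stationary culture last (0.645 and 0.701). Single mouse libraries ranged from 0.480 to 0.637 for N-acetylglucosamine in cecum and from 0.721 to 0.785 for tryptone in feces, and these ranks were not tested.

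A hypothesis was that genes raised on raffinose, stachyose or melibiose, which are galactosides of plants, are raised in mice. Lists of up to 20 genes raised on each sugar were ranked in mouse against culture among 10000 random lists matched to them. The stachyose and melibiose lists lay at percentile 100 in both compartments, and the raffinose list at 98.5 in cecum and 87.61 in feces, so the test left the hypothesis open. High ranks were not particular to galactosides. The xylose, cellobiose, galactose and trehalose lists also lay at percentile 100 in both, and those of N-acetylglucosamine, lactose and arabinose between 99.82 and 100, while the glucose list lay at 9.1 and 91.5 and the sucrose list at 95.2 and 50.9.

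Other splits of the same libraries were counted for the remaining comparisons of 3 or more libraries. For B. thetaiotaomicron feces against cecum, 1 of 100 splits, the real one, gave as many genes (805, the highest other 350). A chance split is thus unlikely but not excluded, since 100 splits allow no smaller share. The splits also took libraries that share a title number as independent. Other comparisons had 10 splits, too few for a share under 0.05. With B. hydrogenotrophica in cecum 2 of 10 splits gave as many B. thetaiotaomicron genes as the real 2, and the highest other was 208, for Bt cecum 1 and 3 with library 9 against the rest, which points to a structure of the samples other than colonisation. For B. hydrogenotrophica against glucose culture 1 of 10 gave as many in cecum (283, the highest other 0) and 1 of 10 in feces (249, the highest other 0). For its feces against cecum the real count was 0 by edgeR (117 at an unadjusted p under 0.05 and 11 by DESeq2, the highest other 2), which makes all 10 of 10 at least as large, so the splits decide nothing there.

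Undepleted cultures were set beside the depleted library of the same culture. Spearman correlations over genes were 0.939 for M. formatexigens xylose 2, 0.934 for B. hydrogenotrophica pyruvate 1, 0.932 for M. formatexigens glucose 1 and 0.661 for B. hydrogenotrophica fructose 2, where 47.4% of genes lay within 2-fold. That undepleted library had 31889 coding reads, against 264630 or more in the others, the 2 depleted fructose libraries correlated at 0.968, and both libraries of fructose 2 carry a description of pyruvate. In repeat cecal libraries the acetogen share of coding reads was 29.2% for M. formatexigens in library 11 (28.4% in its first library) and 7.92% for B. hydrogenotrophica in library 7 (12.2% in its first library). Acetogen reads per gene correlated with those of the first library at a Spearman rho of 0.819 in library 11 and 0.381 in library 7. In single preparations of B. thetaiotaomicron rRNA took from 40.0% to 93.4% of reads on features. In the E. coli libraries it took 80.0% with exonuclease and custom2x treatment and 97.9% without depletion.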
